A study of Mus musculus with 8 samples.

How the data were processed

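Total RNA of quadriceps muscle from male mice was pooled within genotype and sequenced as 8 libraries, per the labels' protocols and the design text: 3 pools from 14 WT mice, 3 from 15 mdx mice and 2 from 11 dy2J mice. Each library was assigned to its group from its label. No sequencing batch or dissection date is given, and which mice entered which pool is not given.

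The authors deposited 1 table of 43628 genes with an FPKM value per library, per the file headers, and the FPKM of each group. The authors' deposited p-value and q-value for mdx against WT and for dy2J against WT stand in the same table, per the file headers. The submitters' processing notes name bcl2fastq 2.15.0.4, Trim Galore 0.3.7, TopHat2 2.0.13, Cufflinks 2.2.1, Cuffnorm, Cuffdiff and the genome build GRCm38, without their settings or order. Whether counting used strand, and how libraries were scaled to each other, is not given in the sources used here. Overlapping, antisense and near-identical genes are therefore uncertain. Cufflinks-type estimates can fail for a gene or locus and are then listed at 0, which was seen for abundant muscle and mitochondrial genes. Of the tested genes, 84 had such a value, and 13, 4 and 5 of them were called in mdx against WT, dy2J against WT and dy2J against mdx. Gene names came from the table, and for 8673 of the 8987 entries without one from GENCODE M21.

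FPKM values hide the number of reads. Low values of 9794 genes with 1 transcript were checked for steps of whole reads, and 23.2% to 31.8% of them lay within 0.1 of a whole multiple of the smallest step, where 20% is chance, so reads could not be recovered and the depth of each library is unknown. Summed FPKM per library ranged from 556218 to 785513, which is not a depth. No interval for counting error is given, and errors are the spread between pools. Mice were pooled, so the spread between mice is not measured. No count model was used because the values are not counts, which is the case foreseen in the plan for normalized values.

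Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1, and fold changes are on that scale, which understates changes of genes at low FPKM. Genes with at least 1 FPKM in at least 2 libraries were kept (12830 genes). All 8 libraries entered 1 linear model with a term per genotype (5 residual degrees of freedom), 3 contrasts were tested with moderated statistics with a mean-variance trend, two-sided, and p-values were adjusted by Benjamini-Hochberg per comparison, with 0.05 as the threshold. An exact permutation test of 1 gene could not pass that threshold, since 3 pools against 3, or 2 against 3, give p of at least 0.1. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

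Lists of genes (35, with 596 symbols, 586 of them found) cover muscle regeneration, fibre types, matrix, immune and other cell types and metabolism. The 33 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. The numbers of lists passing were 16, 23 and 18 in mdx against WT, dy2J against WT and dy2J against mdx. With the correlation estimated from the data camera called 0 lists in each comparison, with 1, 2 and 3 at an unadjusted p under 0.05. The tool fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes, called 19, 15 and 3. Members called were counted over all genes tested and adjusted over the list alone.

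The genes named in the text follow a rule: Dmd, Lama2, Pax7, Pax3, Mamstr and Nnt; in each comparison the 6 largest rises and 6 largest falls among called genes whose groups do not overlap, leaving out predicted and unnamed genes; and the 2 called members with the largest change of each list with at least 3 called members. A gene named in 1 comparison may be given in another. The rule names 123 genes, and the text gives part of them, chosen after their values were seen. Acta1, Pln, Casq2, Adipoq, the Y-linked genes and Xist were chosen after their values were seen, and so were Igf2, Peg3 and the other genes of the closing section that the rule does not name. The lists of the closing section were written after the data were seen. The tests and lists of the report, the rule and all alternatives but 1 were chosen before the data were examined. Treating unreliable values of 0 as missing was chosen after seeing the data, and so were tests of the closing section, as stated there.

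Overlap of the comparisons with WT was set against independent lists and against 50 simulations of unchanged groups that share the WT libraries. Calls near Lama2 and Dmd were compared with calls elsewhere by Fisher's exact test. Alternatives were pseudocounts of 0.1 and 0.5, no expression minimum, a mean FPKM of at least 5, quantile normalization, rescaling by the median ratio, a fit of the compared groups alone, no mean-variance trend, the replicate number as a block, each library left out, a 2-fold minimum, an estimated correlation, fry, the authors' own test and windows of 10 and 40 Mb. Ranges of an adjusted p over the alternatives are of limma's and leave out the authors' test.

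The procedure was tested on simulated data of 12830 genes with 50 genes changed by each of 4 sizes. In mdx against WT it recovered 46% of genes changed by 0.5 on the log2 scale, 92% at 1, 98% at 2 and 90% at -1, in dy2J against WT 12%, 86%, 98% and 90%, and in dy2J against mdx 24%, 84%, 98% and 86%. False calls were 1.81%, 7.74% and 4.58% of calls in the same order. In this simulation, with 200 genes changed, changes of 0.5 in comparisons with dy2J were thus mostly not recovered. In dy2J against WT it called 155 genes, where the data gave 2638. Benjamini-Hochberg adjustment is less strict where more genes change, so recovery in the data may be higher. No unchanged list was called by camera (0 lists), and a list shifted on purpose was called with the preset (adjusted p of at most 2.27e-45) and with the estimated correlation (at most 0.00056). The simulated noise was independent between genes, while the correlation estimated in the data reached 0.868 for oxidative phosphorylation genes. The simulation therefore does not show how often camera calls unchanged lists in data with such correlation.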

Results

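Quadriceps muscle of 40 male mice aged 8 weeks was profiled by RNA sequencing in 3 genotypes. The wild-type group (WT, strain C57BL/10ScSnJ) held 14 mice. The mdx group held 15 mice on the C57BL/10ScSn background with a mutation in Dmd, a model of Duchenne muscular dystrophy. Dmd encodes dystrophin, which links the cytoskeleton of the muscle fibre to its membrane. The dy2J/dy2J group (dy2J) held 11 mice on C57BL/6J with a mutation in Lama2, a model of Lama2-related congenital muscular dystrophy. Lama2 encodes the laminin alpha-2 chain of the fibre's basement membrane. RNA was pooled before sequencing, from 4 to 6 mice per pool in WT and mdx and from 5 to 6 in dy2J, which gave 3 WT, 3 mdx and 2 dy2J libraries. Each n below counts pools, so the p-values of limma measure the spread between pools and not between mice. Camera sets the genes of a list against other genes. Fisher's exact tests and permutations of gene order count genes, which are not replicates, so their p-values do not measure that spread. Values are FPKM (fragments per kilobase of transcript, scaled to the size of the library), and the number of reads behind them is unknown.

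Libraries of the same group resembled each other more than libraries of different groups. Pearson correlations of log2(FPKM + 1) across genes were 0.973 to 0.987 within groups and 0.897 to 0.965 between groups, and no libraries held identical values. The first principal component, with 54% of the variance, placed WT at -46.3 to -32.9, dy2J at 7.95 and 10.5 and mdx at 23.7 to 44.8. The second, with 18.4%, set dy2J (-33.0 and -28.8) apart from the other libraries. Mitochondrially encoded genes took 25.9% to 45.9% of the summed FPKM, with dy2J 1 at 26.0% and dy2J 2 at 45.9%. These shares cannot be compared between pools, because mt-Atp8 was listed at 197760 FPKM in dy2J 2 and at 0 in dy2J 1 and all WT pools. Some values listed at 0 belong to genes that muscle expresses abundantly. Myh4, the main myosin heavy chain of fast fibres, was listed at 0 in all WT pools and in mdx 1, and mt-Co1 in all WT and dy2J pools. In WT 1 all 178 genes overlapping a stretch of chromosome 8 (119910841 to 124345722, GRCm38) were listed at 0, among them Acta1, the skeletal muscle actin gene. No fold change is given for genes with such values.

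Dmd and Lama2, the mutated genes, were examined first. Dmd (ENSMUSG00000045103, chromosome X, 82948870 to 85206141) averaged 29.8 ± 2.01 FPKM in WT (SD, n = 3), 4.58 ± 0.808 in mdx (n = 3) and 25.4 ± 3.76 in dy2J (n = 2). It fell by 2.47 ± 0.13 (SE) on the log2 scale in mdx (limma, Benjamini-Hochberg adjusted p = 1.99e-05). In dy2J it was not called (-0.23, limma adjusted p = 0.293), and the models differed by 2.25 (limma adjusted p = 0.000114). Lama2 (ENSMUSG00000019899, chromosome 10, 26980036 to 27619758) averaged 9.40 ± 0.0505 FPKM in WT, 11.0 ± 1.69 in mdx and 5.19 ± 0.170 in dy2J. It fell by 0.75 ± 0.12 in dy2J (limma adjusted p = 0.00559), was not called in mdx (0.19, limma adjusted p = 0.204), and the models differed by -0.94 (limma adjusted p = 0.00462). Without dy2J 1 the fall of Lama2 in dy2J was 0.78 and did not pass (limma adjusted p = 0.0506). Over the limma alternatives that was the highest value and 0.00173 the lowest, and the authors' deposited table gave q = 0.000749.

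**Figure D1:**
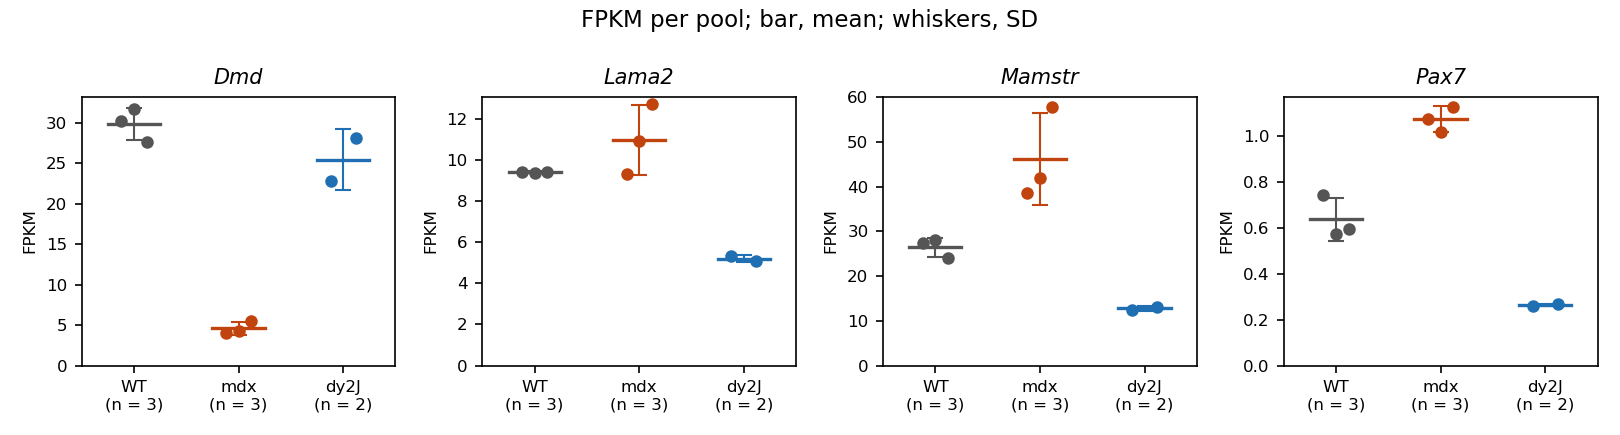
FPKM of Dmd, Lama2, Mamstr and Pax7 in each pool (points), with the group mean (bar) and SD (whiskers), for WT (n = 3), mdx (n = 3) and dy2J (n = 2). Dmd was lowest in the mdx pools (3.98 to 5.50), and Lama2 (5.07 and 5.31), Mamstr (12.4 and 13.2) and Pax7 (0.260 and 0.268) were lowest in the dy2J pools.

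Regulators of muscle stem cells were examined because laminin alpha-2 is part of the satellite cell niche. Mamstr (ENSMUSG00000042918, chromosome 7, 45639977 to 45646521), a co-activator of MEF2 transcription factors, averaged 26.4 ± 2.17 FPKM in WT, 46.1 ± 10.3 in mdx and 12.8 ± 0.581 in dy2J. It rose by 0.76 ± 0.15 in mdx (limma adjusted p = 0.00514) and fell by 0.99 ± 0.17 in dy2J (limma adjusted p = 0.00589). The models differed by -1.75 ± 0.17 (limma adjusted p = 0.00099), a call that held without any 1 library. The fall in dy2J did not pass without dy2J 1 (limma adjusted p = 0.0608, and 0.00178 to 0.0608 over the alternatives). Pax7 (ENSMUSG00000028736, chromosome 4, 139737062 to 139833528), the satellite cell transcription factor, stood at 0.638 ± 0.0933 FPKM in WT, 1.07 ± 0.056 in mdx and 0.264 ± 0.00591 in dy2J. Between dy2J and mdx it differed by -0.71 ± 0.12 (limma adjusted p = 0.0142), but not without dy2J 1 or dy2J 2 or with the replicate number as a block (up to 0.104, and 0.00592 to 0.104 over the alternatives). The rise of Pax7 in mdx (0.34, limma adjusted p = 0.0397) was lost under quantile normalization, median rescaling, a pseudocount of 0.1, the compared groups alone and the block, and without any 1 library other than mdx 2 (up to 0.126, and 0.0169 to 0.674 over the alternatives). In dy2J against WT, Pax7 was not called (-0.37, limma adjusted p = 0.064). It was called there with quantile normalization, a pseudocount of 0.1, no expression minimum, no mean-variance trend, the compared groups alone, without mdx 2 (limma adjusted p from 0.014 to 0.251 over the alternatives) and in the authors' deposited table (q = 0.000749). Pax3, a related factor, was below the expression minimum and not tested, at 0.275 to 0.414 FPKM in WT, 0.267 to 0.414 in mdx and 0.138 and 0.0863 in dy2J. Nnt (ENSMUSG00000025453, chromosome 13, 119335448 to 119408997), a mitochondrial enzyme that makes NADPH and is deleted in part in C57BL/6J mice, averaged 26.9 ± 1.68 FPKM in WT, 18.0 ± 1.93 in mdx and 13.6 ± 0.602 in dy2J. It fell in both models (-0.56 and -0.94, limma adjusted p = 0.00362 and 0.00161), and between them it was not called (-0.38, limma adjusted p = 0.084).

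The comparison of mdx with WT, on the same strain background, asks what the Dmd mutation changes in muscle. Genes of regenerating fibres and of myoblast fusion rose, with a median log2 fold change of 2.99 (camera adjusted p = 1.61e-07, and adjusted p = 0.386 with an estimated correlation). Of 14 tested members 11 were higher and 0 lower, and 11 and 1 adjusted over the list alone. Myl4, a myosin light chain of embryonic muscle, averaged 155 ± 7.99 FPKM in mdx against 3.61 ± 0.94 in WT. Tmem8c, which encodes the fusion protein myomaker, averaged 37.2 ± 12 against 0.463 ± 0.163. Their log2 fold changes were 5.10 and 4.66 (limma adjusted p = 5.33e-07 and 1.21e-05). The myogenic transcription factors Myog (23.7 ± 4.09 against 2.31 ± 0.355 FPKM) and Myod1 (27.9 ± 7.79 against 8.04 ± 0.866) rose by 2.89 and 1.65 (limma adjusted p = 1.21e-05 and 0.000534). Their list, satellite cell and myogenic regulator genes, did not pass as a whole (median 0.57, camera adjusted p = 0.109), with 10 higher and 2 lower of 19, and 10 and 2 adjusted over the list alone.

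Macrophage genes rose in mdx by a median of 2.32 (camera adjusted p = 1.02e-13, and adjusted p = 0.388 with an estimated correlation). Of 25 members 24 were higher and 0 lower, and 24 and 0 adjusted over the list alone. Gpnmb, a glycoprotein of phagocytic macrophages, averaged 53.9 ± 33.4 FPKM against 1.26 ± 0.297, and Lgals3, which encodes galectin-3, 165 ± 73.5 against 9.17 ± 2.44. They rose by 4.41 and 3.97 (limma adjusted p = 0.000231 and 0.000127). All 7 MHC class II genes, which serve antigen presentation, were higher, also adjusted over the list alone (median 1.59, camera adjusted p = 2.35e-05, and adjusted p = 0.386 with an estimated correlation). H2-Aa rose by 1.84 and H2-Ab1 by 1.75. Chemokine and cytokine genes rose, with 14 higher and 1 lower of 20, and 16 and 1 adjusted over the list alone (median 1.27, camera adjusted p = 4.23e-05, and adjusted p = 0.386 with an estimated correlation). Ccl8, which attracts monocytes, reached 53.3 ± 2.26 against 6.19 ± 1.39 FPKM (2.94, limma adjusted p = 3.85e-05). Interferon-response genes rose, with 13 higher and 0 lower of 18, and 15 and 0 adjusted over the list alone (median 0.52, camera adjusted p = 5.56e-05, and adjusted p = 0.388 with an estimated correlation). Complement genes rose, with 9 higher and 0 lower of 11, and 11 and 0 adjusted over the list alone (median 0.76, camera adjusted p = 7.61e-05, and adjusted p = 0.388 with an estimated correlation). Among them C3ar1, the C3a receptor, reached 19.6 ± 10.4 FPKM from 1.39 ± 0.393 (limma adjusted p = 0.000496). Neutrophil genes were not called as a list, with 1 higher and 0 lower of 7, and 0 adjusted over the list alone (median 1.20, camera adjusted p = 0.217). Of the T and NK cell genes 1 reached the expression minimum and of the B cell genes 0, so neither list was tested.

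Fibrillar collagen and matrix genes rose in mdx by a median of 1.05 (camera adjusted p = 7.53e-09, and adjusted p = 0.466 with an estimated correlation). Of 31 members 27 were higher and 0 lower, and 28 and 0 adjusted over the list alone. Postn, which encodes periostin, averaged 124 ± 22 against 9.86 ± 3.02 FPKM (3.54, limma adjusted p = 3.85e-05). Spp1, which encodes osteopontin, rose from 1.12 ± 0.572 to 171 ± 196 FPKM (5.75 ± 0.67, limma adjusted p = 0.000629), with mdx pools at 57.7, 398 and 58.0. TGF-beta and related ligand genes were not called as a list, with 6 higher and 3 lower of 16, and 9 and 3 adjusted over the list alone (median 0.38, camera adjusted p = 0.33). In that list Mstn, which encodes the growth inhibitor myostatin, fell by 1.65, and Tgfb1 rose by 1.51 (limma adjusted p = 0.000185 and 0.00128). Laminin and basement membrane genes were not called either (median 0.25, camera adjusted p = 0.0621), with 4 higher and 0 lower of 15, also adjusted over the list alone. Genes of the dystrophin-glycoprotein complex had 2 higher and 5 lower members of 20, also adjusted over the list alone, and were not called (median -0.07, camera adjusted p = 0.0828). Nos1, the neuronal nitric oxide synthase anchored by that complex, fell by 1.37 (limma adjusted p = 0.000624). Integrin and adhesion genes were not called, with 6 higher and 2 lower of 18, also adjusted over the list alone (median 0.07, camera adjusted p = 0.782). Itga7, the laminin receptor subunit of muscle, rose from 16.1 ± 0.0901 to 32.8 ± 4.45 FPKM (0.97, limma adjusted p = 0.00069).

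Genes of fatty acid uptake and oxidation fell in mdx, with a median of -0.60 (camera adjusted p = 3.34e-10, and adjusted p = 0.386 with an estimated correlation). Of 23 members 0 were higher and 17 lower, and 0 and 20 adjusted over the list alone. Ppara, a transcription factor of fatty acid oxidation, averaged 1.42 ± 0.489 FPKM against 5.21 ± 0.763, and Ppargc1a, a co-activator of mitochondrial genes, 6.62 ± 1.11 against 15.5 ± 2.79. They fell by 1.37 and by 1.11 (limma adjusted p = 0.000646 and 0.00125). Oxidative phosphorylation genes fell as a list, with 0 higher and 9 lower of 45, and 0 and 0 adjusted over the list alone (median -0.35, camera adjusted p = 9.46e-07, and adjusted p = 0.622 with an estimated correlation). Glycolysis and glycogen genes fell too, with 0 higher and 4 lower of 19, and 0 and 0 adjusted over the list alone (median -0.39, camera adjusted p = 0.000438, and adjusted p = 0.622 with an estimated correlation). Endothelial genes fell, with 0 higher and 6 lower of 12, and 0 and 8 adjusted over the list alone (median -0.38, camera adjusted p = 0.00038, and adjusted p = 0.386 with an estimated correlation). Kdr, the VEGF receptor of endothelial cells, averaged 5.01 ± 0.0511 against 8.43 ± 1.19 FPKM (-0.64, limma adjusted p = 0.00304).

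Fast fibre genes fell in mdx, with 1 higher and 5 lower of 15, and 1 and 6 adjusted over the list alone (median -0.38, camera adjusted p = 0.00289, and adjusted p = 0.57 with an estimated correlation). Their mean was 0.10, because the higher member was Myh4, listed at 0 in WT. Myh2, a fast oxidative myosin, fell from 87.6 ± 7.02 to 28.5 ± 1.98 FPKM (-1.59, limma adjusted p = 0.000233). Slow fibre genes moved apart, with 7 higher and 2 lower of 13, also adjusted over the list alone, and were not called as a list (median 0.73, camera adjusted p = 0.105). The slow troponin Tnni1 (68.8 ± 13.2 against 1.49 ± 0.486 FPKM) and Sln, a regulator of the calcium pump (91.7 ± 31.3 against 2.61 ± 1.02), rose by 4.80 and 4.67 (limma adjusted p = 8.75e-06 and 3.85e-05). The slow light chain Myl2 fell from 9.67 ± 0.698 to 4.24 ± 1.44 FPKM (-1.06, limma adjusted p = 0.00519). Calcium handling genes were not called, with 4 higher and 7 lower of 18, and 5 and 7 adjusted over the list alone (median -0.21, mean 0.20, camera adjusted p = 0.202). Apart from Dmd, the largest falls named were Ppp1r1a (-2.72), Slc15a5 (-2.48), Dusp26 (-2.37), Bdh1, an enzyme of ketone metabolism (-2.17), and Ces1d, a lipid hydrolase (-1.99), with limma adjusted p from 1.21e-05 to 0.00105.

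Cell cycle genes rose in mdx, with 17 higher and 0 lower of 20, also adjusted over the list alone (median 1.14, camera adjusted p = 3.53e-05, and adjusted p = 0.57 with an estimated correlation). Cdk1, the mitotic kinase, averaged 5.75 ± 2.69 against 0.643 ± 0.205 FPKM (1.97, limma adjusted p = 0.00113). Apoptosis and p53 target genes rose, with 12 higher and 2 lower of 20, also adjusted over the list alone (median 0.40, camera adjusted p = 0.0129, and adjusted p = 0.386 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, averaged 60.2 ± 8.39 against 9.59 ± 4.12 FPKM (2.60, limma adjusted p = 0.000415). Denervation and neuromuscular junction genes rose, with 9 higher and 1 lower of 19, also adjusted over the list alone (median 0.40, camera adjusted p = 0.00561, and adjusted p = 0.388 with an estimated correlation). Chrng, the fetal subunit of the acetylcholine receptor, reached 12.2 ± 6.70 FPKM from 0.141 ± 0.134 (3.37, limma adjusted p = 0.000599, 2.4e-05 to 0.00405 over the alternatives), but was not called in the authors' deposited table (q = 0.195). Erythroid genes passed narrowly, with 5 higher and 0 lower of 6, also adjusted over the list alone (median 1.12, camera adjusted p = 0.0447, and adjusted p = 0.57 with an estimated correlation). They did not pass without WT 2, mdx 1, dy2J 1 or dy2J 2 (camera adjusted p = 0.06, 0.0959, 0.0518 and 0.0519).

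Further lists were not called in mdx. Adipocyte genes had 0 higher and 1 lower of 12, also adjusted over the list alone (median 0.04, mean -0.09, camera adjusted p = 0.367). Fibro-adipogenic progenitor genes had 5 higher and 0 lower of 12, also adjusted over the list alone (camera adjusted p = 0.143), and Schwann cell genes 1 higher and 3 lower of 7, also adjusted over the list alone (camera adjusted p = 0.165). Tendon genes had 2 higher and 0 lower of 10, and 1 and 0 adjusted over the list alone (camera adjusted p = 0.904). Smooth muscle and pericyte genes had 1 higher and 2 lower of 9, also adjusted over the list alone, with a median of 0.11 but a lower direction in camera (adjusted p = 0.778). Notch pathway genes had 4 higher and 1 lower of 13, also adjusted over the list alone (median -0.02, mean 0.13, camera adjusted p = 0.87). Atrophy and autophagy genes had 3 higher and 2 lower of 19, and 1 and 2 adjusted over the list alone (median -0.04, mean 0.14, camera adjusted p = 0.778). Polyamine metabolism genes had 6 higher and 3 lower of 13, and 6 and 4 adjusted over the list alone (median 0.27, mean -0.01, camera adjusted p = 0.87). Heat shock and immediate-early genes had 6 higher and 3 lower of 12, and 7 and 3 adjusted over the list alone (camera adjusted p = 0.587).

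Of 12830 genes tested, 3069 were higher and 1645 lower in mdx than in WT, so that 65.1% of calls were higher (limma, adjusted p under 0.05). With quantile normalization 2187 were higher and 2947 lower (42.6% higher), and with median rescaling 2561 and 2417 (51.4%), so the balance of higher to lower genes depended on how the libraries were scaled. Quantile normalization moved the median log2 fold change of all genes from 0.07 to -0.07. Changes of at least 2-fold numbered 811 higher and 149 lower.

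The comparison of dy2J with WT asks what the Lama2 mutation changes, but strain differs with genotype here and their effects cannot be separated. Slow fibre genes rose, with the highest median of all lists tested, 3.44 (camera adjusted p = 2.91e-14, and adjusted p = 0.111 with an estimated correlation). Of 13 members 12 were higher and 0 lower, also adjusted over the list alone. Myh7, the slow myosin heavy chain, averaged 71.0 ± 23 FPKM in dy2J against 0.612 ± 0.433 in WT. The slow troponins Tnnc1 (157 ± 49.6 against 2.5 ± 1.95), Tnni1 (115 ± 29.9 against 1.49 ± 0.486) and Tnnt1 (127 ± 12.7 against 2.85 ± 0.926) and Sln (265 ± 29.8 against 2.61 ± 1.02) rose with it. Log2 fold changes of these 5 genes were 5.08 to 6.24 (limma adjusted p from 1.53e-05 to 0.000286). Tnnc1 was not called in the authors' deposited table (q = 0.0592), against 0.000143 to 0.00288 over the limma alternatives. The slow calcium pump Atp2a2 reached 116 ± 9.84 from 11.6 ± 1.04 FPKM (3.21, limma adjusted p = 1.53e-05). Pln, which inhibits that pump, was the member not called (-0.47, limma adjusted p = 0.279).

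**Figure D2:**
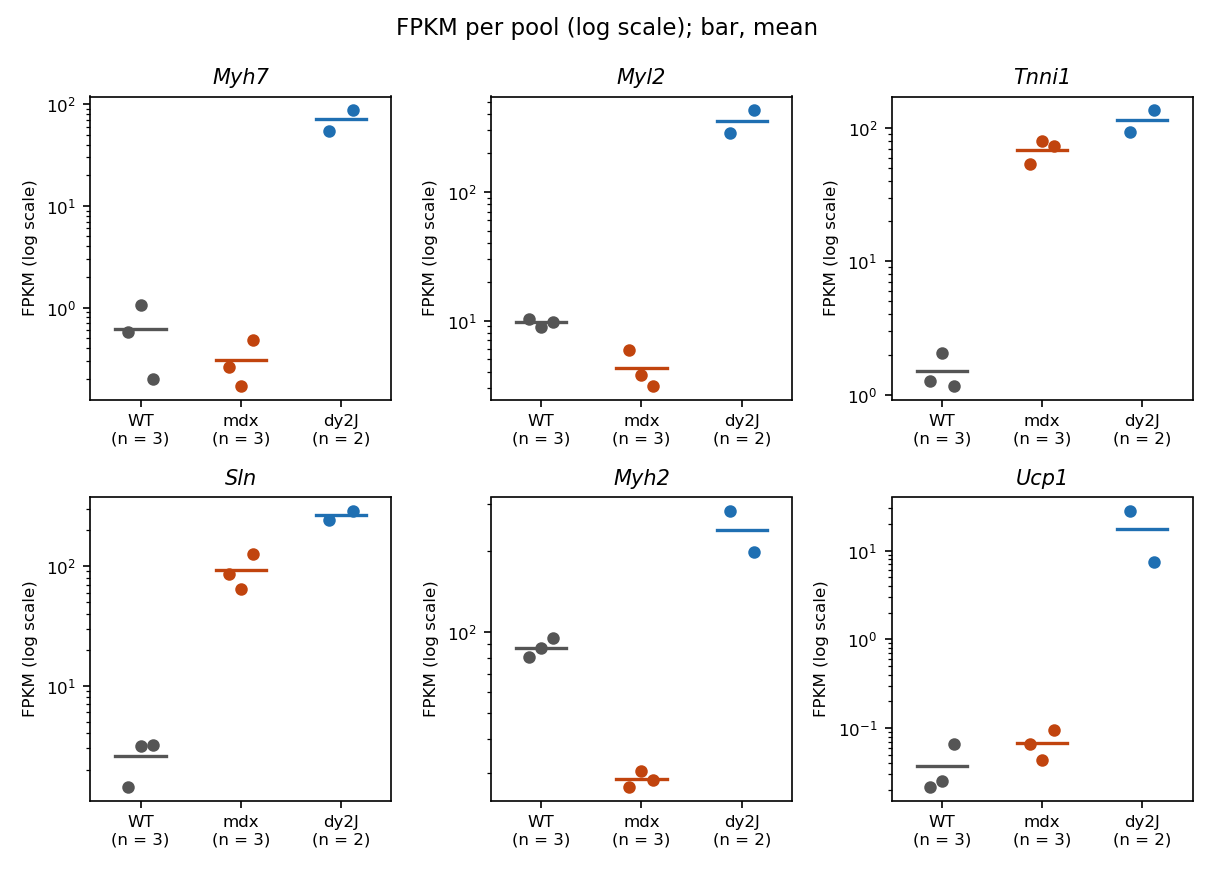
FPKM on a log axis of Myh7, Myl2, Tnni1, Sln, Myh2 and Ucp1 in each pool (points) with the group mean (bar), for WT (n = 3), mdx (n = 3) and dy2J (n = 2). Both dy2J pools lie above every WT and mdx pool for each gene (Myh7 at 54.7 and 87.2), and the mdx pools lie above WT for Tnni1 and Sln and below WT for Myl2 and Myh2.

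Fast fibre genes fell in dy2J, with 2 higher and 10 lower of 15, and 2 and 12 adjusted over the list alone (median -0.82, camera adjusted p = 0.000521, and adjusted p = 0.454 with an estimated correlation). Their mean of 0.10 rests on Myh4, listed at 0 in WT. The other higher member was Myh2, at 240 ± 58.7 against 87.6 ± 7.02 FPKM (1.43, limma adjusted p = 0.00104). Mylk4, a myosin kinase of muscle, fell from 497 ± 75.8 to 103 ± 14.3 FPKM, and Nt5c1a, a nucleotidase, from 16.8 ± 0.594 to 2.74 ± 0.205 (each -2.25, limma adjusted p = 0.000858 and 5.97e-05). Calcium handling genes fell, with 3 higher and 10 lower of 18, also adjusted over the list alone (median -0.69, camera adjusted p = 0.0206, and adjusted p = 0.544 with an estimated correlation). Their mean was 0.13, with Sln, Atp2a2 and Casq2, the calsequestrin of slow fibres, as the higher members (Casq2 not without dy2J 1, limma adjusted p = 0.0518). Glycolysis and glycogen genes fell, with 0 higher and 8 lower of 19, and 0 and 12 adjusted over the list alone (median -0.58, camera adjusted p = 8.69e-05, and adjusted p = 0.544 with an estimated correlation). Phka1, a subunit of phosphorylase kinase, averaged 80.4 ± 11.9 against 186 ± 20.6 FPKM (-1.20, limma adjusted p = 0.00482), and was not called without dy2J 1 (0.0599, the highest over the alternatives).

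Oxidative phosphorylation genes passed as a list in dy2J with 0 of 45 members called by limma, also adjusted over the list alone, 3 lower at an unadjusted p under 0.05 and 1 called in the authors' deposited table (median -0.22, camera adjusted p = 0.00574, and adjusted p = 0.694 with an estimated correlation). Fatty acid uptake and oxidation genes had 0 higher and 2 lower of 23, and 0 and 1 adjusted over the list alone (median -0.16, camera adjusted p = 0.0231, and adjusted p = 0.552 with an estimated correlation). That list did not pass without WT 3 (0.0941). Polyamine metabolism genes were not called as a list, with 1 higher and 4 lower of 13, and 2 and 4 adjusted over the list alone (median -0.03, camera adjusted p = 0.312). The polyamine enzymes Amd1 (24.7 ± 5.11 against 168 ± 47.9 FPKM) and Smox (61.7 ± 11.1 against 282 ± 51.1) fell by 2.69 and by 2.17 (limma adjusted p = 0.00205 and 0.00203). Endothelial genes fell, with 0 higher and 3 lower of 12, also adjusted over the list alone (median -0.29, camera adjusted p = 0.00996, and adjusted p = 0.421 with an estimated correlation).

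Genes of regenerating fibres and of myoblast fusion rose in dy2J by a median of 2.24 (camera adjusted p = 5.28e-11, and adjusted p = 0.378 with an estimated correlation). Of 14 members 12 were higher and 0 lower, also adjusted over the list alone. Myl4 averaged 46.4 ± 1.27 against 3.61 ± 0.94 FPKM and the embryonic myosin Myh3 10.3 ± 3.42 against 0.284 ± 0.1 (3.38 and 3.10, limma adjusted p = 1.53e-05 and 0.00161). Satellite cell and myogenic regulator genes were not called as a list, with 2 higher and 3 lower of 19, and 2 and 4 adjusted over the list alone (median -0.25, mean 0.06, camera adjusted p = 0.437). In that list Myog rose to 14.8 ± 0.885 from 2.31 ± 0.355 FPKM (2.26, limma adjusted p = 0.000121).

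Fibrillar collagen and matrix genes rose in dy2J by a median of 1.39 (camera adjusted p = 2.28e-17, and adjusted p = 0.378 with an estimated correlation). Of 31 members 29 were higher and 0 lower, and 30 and 0 adjusted over the list alone. Postn reached 198 ± 37.7 FPKM (4.22, limma adjusted p = 3.86e-05), and Timp1, an inhibitor of matrix proteases, 40.9 ± 3.67 against 4.49 ± 3.40 (3.15, limma adjusted p = 0.00438, 0.00294 to 0.0498 over the alternatives). Timp1 was not called in the authors' deposited table (q = 0.167). Fibro-adipogenic progenitor genes rose, with 7 higher and 0 lower of 12, and 9 and 0 adjusted over the list alone (median 0.69, camera adjusted p = 5.2e-06, and adjusted p = 0.388 with an estimated correlation). The matrix genes Mfap5 and Lum of that list rose by 1.92 and 1.35 (limma adjusted p = 0.000249 and 0.00121). Tendon genes rose, with 3 higher and 0 lower of 10, also adjusted over the list alone (median 0.55, camera adjusted p = 0.0206, and adjusted p = 0.552 with an estimated correlation), but not without dy2J 1 (median 0.03, camera adjusted p = 0.67). TGF-beta and related ligand genes rose, with 6 higher and 2 lower of 16, and 8 and 2 adjusted over the list alone (median 0.41, camera adjusted p = 0.0442, and adjusted p = 0.544 with an estimated correlation). They did not pass without WT 1, WT 3, mdx 3 or dy2J 1 (camera adjusted p = 0.0747, 0.0523, 0.0544 and 0.165), and their member Mstn fell by 1.68 (limma adjusted p = 0.000474). Genes of the dystrophin-glycoprotein complex fell, with 1 higher and 5 lower of 20, also adjusted over the list alone (median -0.15, camera adjusted p = 0.0328, and adjusted p = 0.552 with an estimated correlation), but not without dy2J 1 (0.108). Laminin and basement membrane genes were not called, with 5 higher and 1 lower of 15, and 6 and 1 adjusted over the list alone (median 0.17, camera adjusted p = 0.0515).

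Macrophage genes rose in dy2J by a median of 1.34 (camera adjusted p = 1.16e-10, and adjusted p = 0.421 with an estimated correlation). Of 25 members 18 were higher and 0 lower, and 22 and 0 adjusted over the list alone. Ctss, a lysosomal protease, averaged 49.8 ± 4.45 against 9.95 ± 1.59 FPKM (2.22, limma adjusted p = 0.00379). MHC class II genes rose, with 6 higher and 0 lower of 7, also adjusted over the list alone (median 1.19, camera adjusted p = 1.19e-05, and adjusted p = 0.378 with an estimated correlation). Complement genes rose, with 9 higher and 0 lower of 11, and 10 and 0 adjusted over the list alone (median 0.83, camera adjusted p = 5.43e-06, and adjusted p = 0.378 with an estimated correlation). Chemokine and cytokine genes rose, with 7 higher and 1 lower of 20, also adjusted over the list alone (median 0.72, camera adjusted p = 0.000784, and adjusted p = 0.421 with an estimated correlation). Interferon-response genes rose, with 8 higher and 0 lower of 18, and 11 and 0 adjusted over the list alone (median 0.40, camera adjusted p = 0.000193, and adjusted p = 0.421 with an estimated correlation). Members of these lists that rose were H2-Ab1 (1.54), the complement factor Cfb (1.57), Ccl8 (2.76) and Cxcl16 (1.82), with limma adjusted p from 0.000158 to 0.00288.

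Heat shock and immediate-early genes rose in dy2J, with 7 higher and 0 lower of 12, and 9 and 0 adjusted over the list alone (median 1.15, camera adjusted p = 0.000327, and adjusted p = 0.421 with an estimated correlation). Fos, an immediate-early transcription factor, averaged 16.7 ± 2.11 against 2.59 ± 0.854 FPKM (2.33, limma adjusted p = 0.00167). Denervation and neuromuscular junction genes rose, with 6 higher and 1 lower of 19, and 9 and 2 adjusted over the list alone (median 0.28, camera adjusted p = 0.0271, and adjusted p = 0.454 with an estimated correlation). Cell cycle genes rose as a list, with 3 higher and 0 lower of 20, also adjusted over the list alone (median 0.65, camera adjusted p = 0.00291, and adjusted p = 0.552 with an estimated correlation). Apoptosis and p53 target genes rose, with 5 higher and 1 lower of 20, and 7 and 1 adjusted over the list alone (median 0.23, camera adjusted p = 0.0206, and adjusted p = 0.378 with an estimated correlation). Cdkn1a averaged 45.8 ± 4.82 against 9.59 ± 4.12 FPKM (2.22, limma adjusted p = 0.00243).

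Adipocyte genes rose in dy2J, with 7 higher and 0 lower of 12, and 9 and 1 adjusted over the list alone (median 1.22, camera adjusted p = 0.00314, and adjusted p = 0.544 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, stood at 27.7 FPKM in dy2J 1 and 7.40 in dy2J 2, against 0.0218 to 0.0942 in the WT and mdx pools (3.90 against WT, limma adjusted p = 0.000863, 4.84e-05 to 0.0066 over the alternatives). Ucp1 was not called in the authors' deposited table (q = 0.306). The fat hormone gene Adipoq was at 65.9 and 57 FPKM in dy2J and at 15.8 to 45.4 in the WT pools. Genes of the Y chromosome stood apart in dy2J. The summed FPKM of Kdm5d, Uty, Ddx3y and Eif2s3y was 16.5 in dy2J 1 and 27.4 in dy2J 2 against 61.5 to 71.5 in the other libraries. Xist, which is transcribed from the inactive X chromosome of females, was at 0.0834 and 0.101 FPKM in dy2J and at 0 elsewhere.

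Further lists were not called in dy2J against WT. Erythroid genes had 4 higher and 1 lower of 6, also adjusted over the list alone (camera adjusted p = 0.0542), and Schwann cell genes 2 higher and 1 lower of 7, also adjusted over the list alone (camera adjusted p = 0.444). Smooth muscle and pericyte genes had 2 higher and 1 lower of 9, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.411). Integrin and adhesion genes had 4 higher and 2 lower of 18, and 4 and 3 adjusted over the list alone (camera adjusted p = 0.45). Neutrophil genes had 0 of 7 called by limma, also adjusted over the list alone, 0 at an unadjusted p under 0.05 and 3 called in the authors' deposited table (camera adjusted p = 0.689). Notch pathway genes had 1 higher and 1 lower of 13 and atrophy and autophagy genes 3 higher and 1 lower of 19, also adjusted over the list alone (camera adjusted p = 0.667 for each).

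In all, 1478 of 12830 genes were higher and 1160 lower in dy2J than in WT (56.0% higher, limma adjusted p under 0.05), and with quantile normalization 1303 and 1658 (44.0%). With 2 dy2J pools these counts depended on single libraries. They were 324 higher and 162 lower without dy2J 1, 762 and 412 without dy2J 2, 907 and 696 without WT 1, 970 and 606 without WT 2, and 990 and 679 without WT 3.

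The direct comparison of dy2J with mdx asks where the models differ, again with strain and genotype confounded. Slow fibre genes were higher in dy2J, with a median of 2.05 (camera adjusted p = 3.01e-17, and adjusted p = 0.0698 with an estimated correlation). Of 13 members 10 were higher and 0 lower, and 11 and 0 adjusted over the list alone. Myl2 averaged 357 ± 103 FPKM in dy2J against 4.24 ± 1.44 in mdx, Myh7 71.0 ± 23 against 0.304 ± 0.16, and the slow light chain Myl3 124 ± 42.9 against 3.44 ± 1.67. They differed by 6.10, 5.76 and 4.86 (limma adjusted p = 1.01e-05, 1.89e-05 and 0.000351). Myh2 was also higher (3.01, limma adjusted p = 3.4e-05), in a fast fibre list that was not called, with 1 higher and 2 lower of 15, and 1 and 3 adjusted over the list alone (median -0.46, mean 0.00186, camera adjusted p = 0.271). Csrp3, a Z-disc protein, was higher at 193 ± 16.1 against 28.5 ± 2.84 FPKM (2.71, limma adjusted p = 2.3e-05). Genes of regenerating fibres and of myoblast fusion were lower, with 2 higher and 4 lower of 14, and 2 and 9 adjusted over the list alone (median -1.11, camera adjusted p = 0.00395, and adjusted p = 0.541 with an estimated correlation). Tmem8c averaged 8.48 ± 0.721 against 37.2 ± 12 FPKM (-1.96, limma adjusted p = 0.00433).

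Satellite cell and myogenic regulator genes were lower in dy2J than in mdx, with 0 higher and 5 lower of 19, and 0 and 8 adjusted over the list alone (median -0.33, camera adjusted p = 0.000383, and adjusted p = 0.187 with an estimated correlation). Besides Mamstr and Pax7, Myod1 was lower, at 11.4 ± 1.03 against 27.9 ± 7.79 FPKM (-1.19, limma adjusted p = 0.0133), and was not called without dy2J 1 or dy2J 2 (up to 0.105, and 0.00952 to 0.105 over the alternatives). Macrophage genes were lower, with 0 higher and 13 lower of 25, and 0 and 24 adjusted over the list alone (median -1.17, camera adjusted p = 1.62e-10, and adjusted p = 0.541 with an estimated correlation). Mmp12, the macrophage elastase, averaged 1.43 ± 0.109 against 37.2 ± 19.1 FPKM (-3.84, limma adjusted p = 0.00099). Gpnmb averaged 4.70 ± 0.109 against 53.9 ± 33.4 FPKM (-3.07, limma adjusted p = 0.00611), and was not called without dy2J 1 (0.0628, and 0.000918 to 0.0628 over the alternatives).

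Chemokine and cytokine genes were lower in dy2J than in mdx, with 1 higher and 2 lower of 20, and 1 and 6 adjusted over the list alone (median -0.62, camera adjusted p = 0.0153, and adjusted p = 0.541 with an estimated correlation). They did not pass without mdx 1 or mdx 2 (camera adjusted p = 0.105 and 0.067). Denervation and neuromuscular junction genes were lower, with 0 higher and 3 lower of 19, and 1 and 7 adjusted over the list alone (median -0.43, camera adjusted p = 0.0394, and adjusted p = 0.541 with an estimated correlation), but not without mdx 2 or dy2J 2 (0.065 and 0.0591). MHC class II genes were lower as a list with 0 of 7 called by limma, also adjusted over the list alone, and 3 lower at an unadjusted p under 0.05 (median -0.40, camera adjusted p = 0.0394, and adjusted p = 0.614 with an estimated correlation), but not without mdx 2, mdx 3 or dy2J 2 (0.0956, 0.056 and 0.327). Cell cycle genes were lower as a list with 0 of 20 called by limma, also adjusted over the list alone, and 8 lower at an unadjusted p under 0.05 (median -0.49, camera adjusted p = 0.00395, and adjusted p = 0.743 with an estimated correlation), but not without mdx 2 (0.145). Polyamine metabolism genes were lower, with 0 higher and 2 lower of 13, and 0 and 4 adjusted over the list alone (median -0.28, camera adjusted p = 0.0127, and adjusted p = 0.353 with an estimated correlation), but not without mdx 1 (0.0967).

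Genes of fatty acid uptake and oxidation were higher in dy2J than in mdx, with 6 higher and 0 lower of 23, and 13 and 0 adjusted over the list alone (median 0.49, camera adjusted p = 1.62e-10, and adjusted p = 0.363 with an estimated correlation). Ppara averaged 4.68 ± 0.566 against 1.42 ± 0.489 FPKM (1.25, limma adjusted p = 0.00676), and was not called without dy2J 1 (0.0769, and 0.00317 to 0.0769 over the alternatives). Adipocyte genes were higher, with 4 higher and 0 lower of 12, and 7 and 0 adjusted over the list alone (median 1.06, camera adjusted p = 1.39e-06, and adjusted p = 0.495 with an estimated correlation). The lipid synthesis enzymes Fasn (120 ± 26.6 against 9.62 ± 0.721 FPKM) and Scd1 (138 ± 4.64 against 18.9 ± 3.99) differed by 3.49 and 2.82 (limma adjusted p = 0.00141 and 0.00291). As in the comparison with WT, Ucp1 was higher (3.86, limma adjusted p = 0.00152). Oxidative phosphorylation genes were higher as a list with 0 of 45 called by limma, also adjusted over the list alone, and 3 higher at an unadjusted p under 0.05 (median 0.14, camera adjusted p = 0.000784, and adjusted p = 0.764 with an estimated correlation). Without mdx 2 their median was -0.06 (camera adjusted p = 0.843).

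Fibro-adipogenic progenitor genes were higher in dy2J than in mdx, with 4 higher and 0 lower of 12, and 6 and 0 adjusted over the list alone (median 0.44, camera adjusted p = 1.39e-06, and adjusted p = 0.363 with an estimated correlation). Heat shock and immediate-early genes were higher, with 4 higher and 0 lower of 12, and 5 and 0 adjusted over the list alone (median 0.50, camera adjusted p = 1.59e-05, and adjusted p = 0.363 with an estimated correlation). Schwann cell genes were higher, with 3 higher and 0 lower of 7, and 3 and 1 adjusted over the list alone (median 0.14, camera adjusted p = 0.00649, and adjusted p = 0.363 with an estimated correlation). The myelin gene Mbp (8.53 ± 0.597 against 3.37 ± 0.752 FPKM) differed by 1.14 (limma adjusted p = 0.00601). Mbp was not called without dy2J 1 or dy2J 2 (up to 0.0548, the highest over the alternatives). Fibrillar collagen and matrix genes were higher, with 2 higher and 0 lower of 31, and 5 and 1 adjusted over the list alone (median 0.38, camera adjusted p = 2.99e-06, and adjusted p = 0.548 with an estimated correlation), but not without dy2J 1 (0.44). Tendon genes were higher as a list with 0 of 10 called by limma, also adjusted over the list alone, and 4 higher at an unadjusted p under 0.05 (median 0.56, camera adjusted p = 0.0011, and adjusted p = 0.541 with an estimated correlation). Without dy2J 1 their median was -0.06 (camera adjusted p = 0.653). Endothelial genes were higher as a list with 0 of 12 called by limma, also adjusted over the list alone, and 2 higher and 1 lower at an unadjusted p under 0.05 (median 0.15, camera adjusted p = 0.0429, and adjusted p = 0.541 with an estimated correlation), but not without mdx 1, mdx 2, dy2J 1 or dy2J 2 (0.0576, 0.0862, 0.0549 and 0.118).

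In all, 15 lists were not called between dy2J and mdx, with camera adjusted p from 0.126 for smooth muscle and pericyte genes to 0.821 for complement genes. For laminin and basement membrane, dystrophin-glycoprotein complex, integrin and adhesion, and atrophy and autophagy genes the median was below 0 (-0.02, -0.13, -0.05 and -0.01) while camera gave a higher direction. Complement genes had a median of 0.04 and a mean of -0.20.

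**Figure D3:**
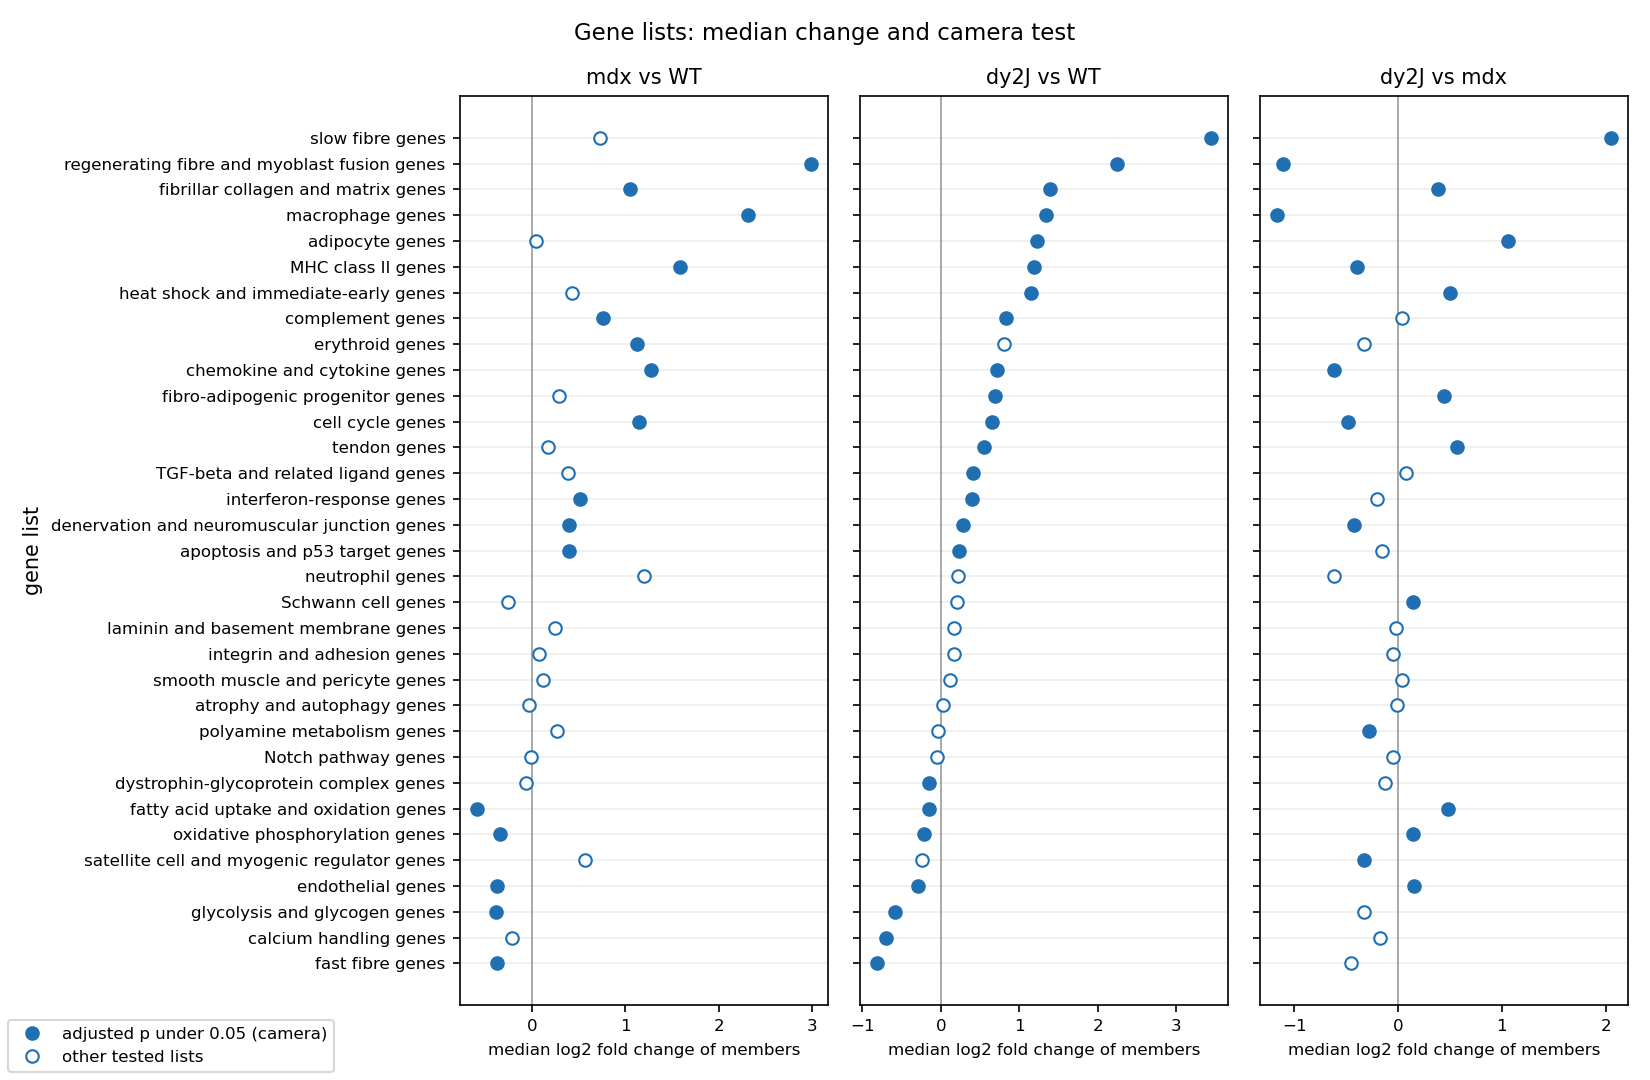
Median log2 fold change of the tested members of each gene list (horizontal axis) in the 3 comparisons. Filled points mark lists that passed camera at an adjusted p under 0.05 with the preset correlation and open points those that did not, and the slow fibre list has the highest median in dy2J against WT (3.44) and in dy2J against mdx (2.05).

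Between dy2J and mdx 356 genes were higher and 469 lower (43.2% higher, limma adjusted p under 0.05), with quantile normalization 695 and 480 (59.1%) and with median rescaling 589 and 393 (60.0%). Without dy2J 1 there were 84 higher and 60 lower, and without dy2J 2 157 and 81. The number lower also moved by over 1.5 times without WT 2 (296), WT 3 (295), mdx 1 (864) and mdx 3 (281).

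The comparisons with WT overlapped. Of the 12830 genes, 1139 were higher in both models and 740 lower in both, where independent lists of these sizes would share 353.5 and 148.7. In opposite directions 34 were called. Across genes, which are not independent replicates, the log2 fold changes had r = 0.71, where unchanged groups simulated against the same WT libraries gave 0.449. Their covariance was 0.232 against a simulated 0.0171, a difference of 0.215. The 3 WT libraries were too few to split, so part of the excess over independent lists may come from the shared controls. Numbers higher and lower in both were 661 and 421 without WT 1, 720 and 374 without WT 2, 715 and 412 without WT 3, 259 and 107 without dy2J 1, and 599 and 293 without dy2J 2. In dy2J 183 genes were above both WT and mdx, and 130 below both.

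Genes near the mutated loci were compared with genes elsewhere by two-sided Fisher's exact tests. Within 20 Mb of Lama2, 30 of 137 tested genes were called in dy2J against WT (21.9%, elsewhere 20.7%), with an odds ratio of 1.07 (95% interval 0.688 to 1.62, Fisher's exact test, p = 0.751). Within 20 Mb of Dmd, 34 of 106 were called in mdx (32.1%, elsewhere 37.3%), with an odds ratio of 0.793 (0.511 to 1.21, Fisher's exact test, p = 0.313). Counting only changes of at least 2-fold, the odds ratio near Lama2 was 2.14 (Fisher's exact test, p = 0.0139).

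The authors' deposited table called 3906 genes in mdx (2739 higher, 1167 lower) and 2725 in dy2J (1742 higher, 983 lower) at q under 0.05. Of these genes of the authors' deposited table, 3451 and 2469 were among the genes tested here. Of those, 3173 and 1847 were also called here, all in the same direction.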

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

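The tests of heart muscle, of scaling, of a slower part of the muscle and of white fat were chosen only after the result was seen, and the tests of brown fat and of other splits of the libraries before.

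Of the 123 genes named by the rule, 7 changed in opposite directions against WT in mdx and in dy2J, and each of these 7 also differed between the models by the limma contrast of dy2J with mdx (limma adjusted p from 1.01e-05 to 0.00601). Myl2 differed by 6.10, with -1.06 in mdx (limma adjusted p = 0.00519) and 5.04 in dy2J (limma adjusted p = 1.53e-05). Myl3 differed by 4.86, with -1.42 (limma adjusted p = 0.0117) and 3.44 (limma adjusted p = 0.00104). Myh2 differed by 3.01, with -1.59 (limma adjusted p = 0.000233) and 1.43 (limma adjusted p = 0.00104). Erdr1, a gene of the pseudoautosomal region, differed by 3.39, with -1.42 (limma adjusted p = 0.00383) and 1.98 (limma adjusted p = 0.00363). Scd1, a fatty acid desaturase gene, differed by 2.82, with -1.50 (limma adjusted p = 0.00516) and 1.32 (limma adjusted p = 0.0254), the second not without WT 2, dy2J 1 or dy2J 2 (up to 0.15). Mamstr differed by -1.75, with 0.76 (limma adjusted p = 0.00514) and -0.99 (limma adjusted p = 0.00589), the second not without dy2J 1 (0.0608). Mbp, the gene of myelin basic protein, differed by 1.14, with -0.61 (limma adjusted p = 0.0109) and 0.53 (limma adjusted p = 0.0458), and neither the difference without a dy2J library (up to 0.0548) nor the change in dy2J without a WT or a dy2J library (up to 0.20) was called.

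Myl2 and Myl3 belong to a pattern in which slow fibre genes were higher in dy2J than in WT and mdx. Heart muscle in the sample is argued against, because the summed FPKM of 5 heart genes (Myh6, Nppa, Nppb, Myl7 and Tnni3) was at most 2.37% of Myh7 in the dy2J pools, and scaling is too, because the slow fibre list kept a median of at least 3.42 under quantile normalization and median rescaling. A slower part of the quadriceps, or a neighbouring slow muscle, in the dy2J samples stays open, because the labels do not record where in the muscle the samples were taken. That limma called 0 of 13 slow fibre genes lower (0 in the authors' deposited table, and 0 at an unadjusted p under 0.05) restates the pattern and does not test this. The ratio of dy2J 1 to dy2J 2 ran from 0.608 for Myl3 to 1.01 for Myoz2 among 11 of the 12 called members. It was 1.41 for Casq2, which rose in mdx too (1.42). A single such source would make the ratio alike only for genes with little other expression. Myh7, Myl2 and Myl3, at most 12.3 FPKM in each WT and mdx pool, had 0.627, 0.662 and 0.608. The other called members, above that in at least 1 of these pools, had 0.635 (Tnnc1) to 1.41, so the ratios do not decide this. A shift of fibres toward the slow type with the Lama2 mutation, and a difference between strains, also stay open, since genotype and strain are confounded.

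Scd1 belongs to a pattern in which adipocyte and lipid synthesis genes were higher in dy2J. More white fat alone is argued against as the cause of the rise of Fasn, because the upper quartile of 14 white fat genes rose by 1.18 where Fasn rose by 2.99. Those 14 genes as a list did not pass against WT (5 higher and 1 lower, camera p = 0.157, and p = 0.621 with an estimated correlation). Without WT 1 or WT 2 only Retn of the 5 was still called. Against mdx 2 were higher and 0 lower (camera p = 2.28e-06, and p = 0.139 with an estimated correlation). Brown fat in the dy2J samples is a candidate explanation for Ucp1 and Cidea (Ucp1 27.7 FPKM in dy2J 1 and 7.4 in dy2J 2, Cidea 14.9 and 5.38, at most 2.40 elsewhere), because 3 of 6 further brown fat genes under 1 FPKM in each WT pool reached 1 FPKM in dy2J 1. The other 9 genes reached 1 FPKM in at least 1 WT pool, among them Zic1, which was lower in dy2J (0.102 and 0.254 FPKM against 0.272 to 1.02), and the brown fat list as a whole was not called against WT (3 higher and 2 lower of 12, median -0.10, with a camera p of 0.799) but was against mdx (4 higher and 0 lower, with a camera p of 3.67e-06, and 0.0734 with an estimated correlation), where only Ucp1 of the 4 was still called without dy2J 1 and 2 without mdx 3, and where Ppara and Cpt1b had fallen in mdx (-1.37 and -0.97) and were not higher in dy2J than in WT (-0.12 and -0.46). The 3 were Dio2 (4.83 FPKM, but 1.53 to 1.86 in mdx, where Ucp1 was at most 0.0942, so that it is no sign of brown fat alone), Otop1 (1.26) and Slc27a2 (1.17), lower in dy2J 2 (2.68, 0.652 and 0.361), and an untested effect of the mutation or of strain on fat stays open.

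Chance was examined by other splits of the 6 WT and mdx libraries, of which there are 10, too few for a share under 0.05. The real split called 4714 genes by limma and the highest of the other splits 2, so that 1 split of 10 gave as many. Each other split mixes WT and mdx libraries within its groups, so the difference between genotypes adds to the spread and lowers its calls. The 2 genes are thus no measure of how many calls chance would give. For lists, where the real split called 16 by camera, 3 splits of 10 gave as many and the highest other called 17.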

How the results depend on the processing

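Treating unreliable values of 0 as missing was chosen only after the data were seen. No called gene or list was called in the opposite direction under any alternative run. A model without the trend, pseudocounts of 0.1 and 0.5 and zeros as missing left the counts of genes, lists and overlaps within 1.5 times and Dmd and Lama2 called. The authors' test, which gives no list tests, did so for genes and overlaps in the comparisons with WT. Calls near Dmd and Lama2 did not differ from calls elsewhere under any alternative but the 2-fold minimum, with odds ratios on both sides of 1, also with windows of 10 and 40 Mb (1.46 and 0.844 near Lama2). With a mean FPKM of at least 5, which tests 7376 genes, 1623 genes were higher in mdx and 284 lower in dy2J than in mdx. Without an expression minimum (24600 genes tested) 752 were lower in dy2J than in WT, 234 lower in dy2J than in mdx, and 740 higher in both models. With quantile normalization 2947 genes were lower in mdx, 695 higher in dy2J than in mdx and 1220 lower in both models, and with median rescaling 589 were higher in dy2J than in mdx. For scaling the cause was not tested. Fitting dy2J and mdx alone, with fewer libraries, left 208 higher and 188 lower. By construction a 2-fold minimum left fewer calls: 811 and 149 in mdx, 456 and 149 in dy2J, 130 and 160 between the models, and 245 and 42 in both. Under it Lama2 (-0.749) no longer counted as called in dy2J, and the odds ratio near Lama2 was 2.14 (Fisher's exact test, p = 0.0139), for which the cause was not tested. Camera with an estimated correlation called 0 lists in each comparison (1, 2 and 3 at an unadjusted p under 0.05), and fry 15 in dy2J against WT and 3 in dy2J against mdx. Of the 57 lists that camera called, fry did not call 27. In mdx these were 3 (fast fibre, oxidative phosphorylation and glycolysis genes, fry adjusted p from 0.0605 to 0.169). In dy2J they were 9, with fry adjusted p from 0.078 to 0.534: TGF-beta, dystrophin complex, oxidative phosphorylation, fatty acid, glycolysis, adipocyte, tendon, cell cycle and calcium handling genes. Between the models they were 15 of 18 (fry adjusted p from 0.0548 to 0.639). For fry, which compares no list with other genes, the cause was not tested.

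With the replicate number as a block, 618 genes were lower in dy2J than in WT, 265 lower in dy2J than in mdx and 417 lower in both models, and the other counts stayed within 1.5 times. It ended 13 calls among 174 results of named genes, counted per gene and comparison, and 2 of 57 list calls. Deviations of same-numbered libraries from their group means had r from -0.15 to 0.085 (7 pairs). Deviations within a group cancel out, so dy2J 1 and dy2J 2 mirror each other and the pairs are not independent checks. A batch shared by same-numbered libraries is thus neither shown nor excluded.

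Leaving out each library in turn gave 2367 to 3131 genes higher and 1110 to 2024 lower in mdx, 324 to 1826 and 162 to 1480 in dy2J, and 84 to 342 and 60 to 864 between the models. Genes higher in both models numbered 259 to 1296 and lower 107 to 951, and lists called 15 to 18, 21 to 24 and 14 to 18. The odds ratio of calls near Lama2 was 0.999 to 1.58 and near Dmd 0.814 to 1.06. The change of Dmd in mdx was -2.59 to -2.40 and of Lama2 in dy2J -0.777 to -0.721, with the first value, without dy2J 1, not called (limma adjusted p = 0.0506). Without a dy2J library the remaining 1 is assumed to vary like the other groups. Of named genes called, 62 of 70 in mdx, 33 of 64 in dy2J and 16 of 38 between the models were called in each fit that left out 1 library. Of 57 lists called, 43 were called in each such fit and 14 were not, and 9 of 53 were lost with a mean FPKM of at least 5, 3 in the fit of the compared groups alone, 2 with quantile normalization and 1 with a pseudocount of 0.1. Alternatives for count tables and for tables with group values alone were not run, since the table holds FPKM per library. Depth is unknown and sets no limit that can be stated.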

Other observations

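The tests of the Y-linked genes, the restriction of the test of genome segments to pairs that do not overlap, and the comparison of the median of Bmal1-phase genes with their SD were chosen only after the result was seen, and the tests of imprinted genes, fatty acid synthesis and clock genes before their lists were tested.

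Igf2, an imprinted growth factor, rose in mdx from 6.60 ± 1.05 to 111 ± 21.2 FPKM (3.88, limma adjusted p = 6.14e-06, SD, n = 3), and Peg3, an imprinted zinc finger gene, from 7.39 ± 1.09 to 26.2 ± 2.97 (1.70, limma adjusted p = 0.000127). In dy2J Igf2 rose by 1.93 (limma adjusted p = 0.000418), 1.95 less than in mdx (limma adjusted p = 0.000588). Of 21 other entries of imprinted genes tested in mdx, which hold Snrpn as 2 overlapping entries, limma called 8 higher and 4 lower (1 entry of Snrpn among the latter). Mest, Grb10 and Cdkn1c rose by 1.63, 1.15 and 1.10, while Nnat and Asb4 fell by 1.70 and by 0.84 (limma adjusted p from 0.000411 to 0.0108). The hypothesis that imprinted genes as a group are higher in mdx found no support and stays open, with a camera p of 0.457 and a median of 0.17. A p of 0.05 or more had been set beforehand as evidence against it, but that bound was wrong, because such a p does not show that genes did not differ.

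Lipid synthesis genes rose with Fasn, which averaged 120 ± 26.6 FPKM in dy2J and 15.4 ± 8.58 in WT (2.99, limma adjusted p = 0.00143). Elovl6, which lengthens fatty acids, rose by 1.84, Slc25a1, the citrate carrier, by 2.16, and Acly, which makes acetyl-CoA from citrate, by 1.52 (limma adjusted p = 0.000351, 0.00215 and 0.000875). Of 20 genes of fatty acid synthesis other than Fasn and Scd1, limma called 9 higher and 3 lower, among the latter Lpin1 (-1.03, limma adjusted p = 0.0029). Of these, 5 higher and 1 lower were still called without dy2J 1, and 7 and 1 without dy2J 2. A joint rise of the pathway in dy2J may be a candidate explanation (camera p = 0.00579) but stays open, because the p was 0.296 with an estimated correlation. Between dy2J and mdx 10 of these genes were higher and 0 lower (camera p = 1.47e-13, and p = 0.026 with an estimated correlation), of which 2 were still called without dy2J 1 and 5 without dy2J 2. Part of this difference was a fall in mdx, where the list had 1 higher and 8 lower against WT (camera p = 0.00842, and p = 0.316 with an estimated correlation). Among the 10 genes Acss2, Dgat2 and Me1 fell in mdx (-0.56, -0.88 and -0.99) and were not called in dy2J against WT (0.19, 0.30 and -0.26).

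Clock genes of the phase opposite to Bmal1 were lower in mdx (6 of 10 lower, median -0.60, camera p = 0.000106, and p = 0.0977 with an estimated correlation) and in dy2J (7 of 10 lower, median -0.93, camera p = 1.13e-05, and p = 0.0695 with an estimated correlation). Among them Bhlhe41 fell by 0.76 and by 1.27 and Hlf by 1.48 and by 1.66 (limma adjusted p = 0.00296, 0.00133, 0.00927 and 0.0171), Hlf in dy2J not without dy2J 1 or dy2J 2 (up to 0.121). Of the 7 in dy2J, 2 were still called without dy2J 1 and 4 without dy2J 2. A different time of dissection would move genes of the Bmal1 phase the opposite way, with at least 2 called in each phase. In mdx this is argued against, if both phases move by about as much: the 6 genes called were all of the other phase, and limma called 0 of 5 Bmal1-phase genes (0 at an unadjusted p under 0.05, 0 in the authors' deposited table). These had a median of -0.02 (-0.33 to 0.21, SD 0.21), where a rise of about the size of the other phase's -0.60 was needed, and changes of 0.5 were recovered in 46% of simulated genes. Whether both phases move by as much was not tested, and in dy2J their medians were 0.52 and -0.93. A time difference that moves the Bmal1 phase less is therefore not excluded in mdx. In dy2J the explanation may hold and stays open: 8 genes were called in the predicted directions, with only Npas2 of the Bmal1 phase (0.85, limma adjusted p = 0.0135, lost without dy2J 1 or dy2J 2, up to 0.0892). Nr1d1 of the other phase was called lower in mdx (-1, limma adjusted p = 0.00493) and not in dy2J. In dy2J it was 1.01 above mdx (limma adjusted p = 0.0319, lost without WT 2, mdx 2, mdx 3, dy2J 1 or dy2J 2). The demand for 2 genes, set beforehand, may have been too strict in dy2J, where the Bmal1 phase had a median of 0.52. Changes of 0.5 were recovered there in only 12% of simulated genes, but the simulation changed fewer genes than the data and so understates recovery.

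Y-linked genes were lower in both dy2J pools. The summed FPKM of 4 genes was 25.7% of the WT mean in dy2J 1 and 42.8% in dy2J 2, and Ddx3y, a helicase gene, fell by 1.46 (limma adjusted p = 0.000418). A fixed difference of the Y chromosome between strains is argued against as the whole cause, because the dy2J pools differed from each other by a ratio of 1.66, against at most 1.15 between pools of WT or of mdx. RNA of female mice in the pools could lower these genes and stays open, because no female library shows the levels it would need, and an effect of the mutation was not tested. Xist reached 0.101 FPKM at most (0 in the other libraries) and was not higher in the pool with less Y-linked RNA. Of the X-linked partners, Kdm5c was at 11.1 and 8.14 FPKM in dy2J 1 and dy2J 2, against 5.12 to 5.73 in WT and 6.3 to 7.81 in mdx. Eif2s3x was at 40 and 42.3, against 28.4 to 33.8 in WT and 30 to 36.5 in mdx. Kdm6a was at 4.33 and 4.36, against 4.32 to 4.46 in WT and 3.81 to 4.52 in mdx. Ddx3x was at 58.5 and 64.3, against 59.6 to 63.2 in WT and 44.1 to 52.9 in mdx.

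Strain was examined through the order of genes on the chromosomes, since differences carried in genome segments could put changed genes next to each other. Of 304 placed genes by which dy2J differed from both WT and mdx, 19 pairs were adjacent, against a mean of 7.38 in 10000 permutations of gene order (p = 1e-04, the smallest they can give). Without the Y chromosome and overlapping pairs there were 7, against 6.26 (permutation p = 0.433). For genes by which mdx differed from both, where WT shares the strain background, the pairs were 30 against 18.7 (permutation p = 0.0079) and 23 against 16.4 (permutation p = 0.066). The test leaves the strain open, because the count depends on the restriction and genes that set mdx apart, without a strain difference from WT, were adjacent more often than permuted genes too.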
